A study of Homo sapiens with 2 samples.

How the data were processed

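RNA from HK-2 cells was hybridised to 1 single-channel array per condition, 1 after 10 µM aristolochic acid for 24 h and 1 for untreated control cells. Per the labels' protocols, total RNA was extracted with an RNeasy kit, amplified and labelled with a MessageAmp aRNA kit and the dye Cy5, and the cells grew in keratinocyte serum-free medium with epidermal growth factor and bovine pituitary extract. The series' design text says that control cells received water alone. The growth text of the control sample repeats the sentence on adding aristolochic acid, but its title and characteristics name no agent, and the sample was taken as the control on that ground. The design text prints 10 and 90 µM as doses, and samples at doses other than 10 µM were not analysed here.

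The deposited values are log10 probe levels, a base read from the values and not stated in the sources used here. As powers of 10 the highest values were 66543 linear units in the aristolochic acid array and 53864 in the control, close to 65535, the ceiling of a 16-bit scanner, and on this reading the former lies above that ceiling. The scanner's bit depth is an assumption here. If the base were another, every log2 difference would change by a constant factor. The submitters' processing notes name limma with no version or role. Background correction, normalisation, scanner, image analysis and the filter that left 20257 probes are not given in the sources used here. In the control array 9409 values were written with 5 decimals and in the other array 0.

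Values were converted to log2. The arrays' medians differed by -0.01 and their interquartile ranges by 0.03 on the log2 scale, below the limit of 0.1 set for tables that need no further scaling, so the values were used as deposited. Probe identifiers were matched exactly to a reference table of gene symbols, and older symbols were replaced by current ones (8285 current, 1989 updated, 47 left as they were). Of the probes, 10321 had 1 symbol, 0 had several and 9936 had none, and the latter entered no comparison between genes. Each of the 9273 genes was represented by its brightest probe, and 8281 genes had a single probe. No genome build is named in the sources used here and no coordinates were used.

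The names of the probes were checked by further comparisons, chosen after the data had been seen. The levels of both brightest probes of a gene correlated with r = 0.13 over 992 genes, against -0.09 to 0.08 when the names were shifted along the probe list by up to 50 places. Of 18 measured genes for heterogeneous nuclear ribonucleoproteins, abundant in all dividing cells, 15 (83.3%) were among the brighter genes, against 4 of 31 (12.9%) hair keratin-associated genes, and 3 of 8 cytosolic ribosomal protein genes (37.5%). The share was 65.2% for mitochondrial ribosomal proteins and 57.9% for translation initiation factors, against 21.3% for interleukins and their receptors, 25.3% for potassium channels and 21.4% for kallikreins. The 7 measured housekeeping genes had a median level of 6.23 log2, below the 7.45 of all named genes. For the 7 measured genes of the loop, distal tubule and collecting duct it was 8.87. These values do not settle how far the names hold: the ribosomal protein genes, abundant in most cells, were mostly dim, and probes of a gene were only weakly alike in level. A gene's value here means the value of the probe with its name.

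With 1 array per condition there is no replicate error, no p-value was computed, and no array can be left out. No paired analysis was possible because each condition has a single array. The number of arrays limits the precision, and no detection or background value was used. The difference of a gene is its log2 level after aristolochic acid minus that in the control. Genes at least 2-fold apart were counted among the brighter genes, those with a mean level over both arrays at or above the median of named genes (7.45 log2, 174.9 linear units).

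Before the data were examined, 42 gene lists, the rule for named genes and the alternatives were fixed, except where the text says otherwise. Lists covered DNA damage and repair, cell cycle, oxidative and other stress responses, metabolism of aristolochic acid, inflammation, matrix, energy and lipid metabolism, kidney segments, other cell types and reference genes. A list's value is the median difference of its brighter members, or of all measured members where fewer than 5 were brighter (9 lists), with its percentile among 10000 random lists of the same size drawn in 10 bins of level (seed 20). Lists with fewer than 3 measured members got no value, and the result of 1 list and of some genes is not reported here. The named genes are the 10 highest and 10 lowest brighter genes, up to 2 brighter members of each list outside the central 95% of random lists, and 34 genes chosen for aristolochic acid and tubular injury. Other members are given as examples of their lists and were chosen after their values were seen.

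The list method was tested on simulated data. Among 200 random lists of 8 genes with no added shift, 6% lay outside the central 95%, and 28%, 70% and 100% did so after a log2 shift of 0.25, 0.5 and 1. For 15 genes the shares were 7%, 36%, 84% and 100%. The simulated differences were centred, shuffled among genes of like level and given random signs, so a skew of the real differences was absent. Every member of a list took the same shift. All simulated lists were drawn from the brighter genes, so the method was not tested for lists over all measured members.

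Alternatives were subtraction of each array's median, quantile normalisation, removal of the trend with level by loess (span 0.4), the mean of all probes of a gene, a pseudocount of 35.8 linear units (the 25th percentile of the values), no filter on level, the brightest 25% of genes, thresholds of 1.5-fold and 3-fold, random lists without matching or with 20 bins, and the mean of list members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.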

Results

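The series measured gene expression in HK-2 cells, an immortalised line of proximal tubule epithelial cells from a normal adult human kidney. The cells received aristolochic acid, a nitrophenanthrene carcinogen and kidney toxin of Aristolochia plants, or no aristolochic acid. The sodium salt used was a mixture of aristolochic acid I (41%) and aristolochic acid II (56%). There were 2 single-channel arrays, 1 from cells exposed to 10 µM for 24 h and 1 from untreated control cells, so no value given here has a replicate and no difference has been set against a spread between cultures. The deposited table held 20257 probes, of which 10321 carried a gene symbol in the reference used here, and these named 9273 genes. Across all probes the levels of both arrays correlated with a Pearson r of 0.973 and a Spearman rho of 0.965, where probes are not independent replicates.

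The comparison asks how expression in these tubular cells differed after aristolochic acid. The probe for INSM2, a zinc finger transcription factor, had the largest difference, with a level of 3934 linear units after aristolochic acid against 23.6 in the control. Its log2 difference was 7.38, and 6.06 with a pseudocount of 35.8 linear units, which exceeds the control level. SDHAF3, an assembly factor of succinate dehydrogenase, was 19.7-fold higher (1950 against 98.8 linear units), CD244, a receptor of natural killer cells, was higher by 4.13 on the log2 scale and FGFR1, a fibroblast growth factor receptor, by 3.63. At the other end stood LRRC14 with a log2 difference of -4.22 (281 against 5244 linear units), the fatty acid desaturase family gene FADS6 with -4.02 and the scaffold gene CASKIN2 with -3.98. JUND, a subunit of the AP-1 transcription factor, was 8.03-fold lower at 131 against 1052 linear units, and MAP2K7, a kinase that activates JUN N-terminal kinase, had a log2 difference of -3.37.

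The rest of the 10 highest among the brighter genes were TMEM106B, LRRN2, HAPLN2, LSM14B, BTBD10 and the cannabinoid receptor gene CNR1, with log2 differences from 3.31 down to 2.54. FAM221B, CTDSPL, OGFOD1, the Golgi SNARE gene GOSR2 and MDGA1 completed the 10 lowest among the brighter genes, between -3.54 and -2.88. Of the 10 highest, all but LRRN2 (418.7 linear units) had a control level below 174.9 linear units, the cut for the brighter genes. These control levels ran from 23.6 for INSM2 to 152.2 for LSM14B, so these genes passed the cut through the aristolochic acid array. Of the 10 lowest, OGFOD1 and JUND were below it after aristolochic acid, at 113.0 and 131.0. In each of these groups of 10, 9 genes rested on 1 probe. LSM14B and GOSR2 had further probes: the second brightest probe of LSM14B differed by 0.26 where the brightest differed by 2.74, and for GOSR2 the values were -1.26 and -3.25.

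Among the 4637 genes whose mean level over both arrays was at or above the median of named genes, called the brighter genes from here on, 170 (3.67%) were at least 2-fold higher after aristolochic acid and 281 (6.06%) at least 2-fold lower. The other 4186 genes (90.3%) lay within 2-fold. The log2 differences had a median of 0.00 and an SD over genes of 0.65, and their central 95% ran from -1.38 to 1.13. Without the filter on level, 545 of 9273 genes were at least 2-fold higher and 584 at least 2-fold lower, so that 48.3% of these genes were higher, against 37.7% among the brighter genes.

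**Figure D1:**
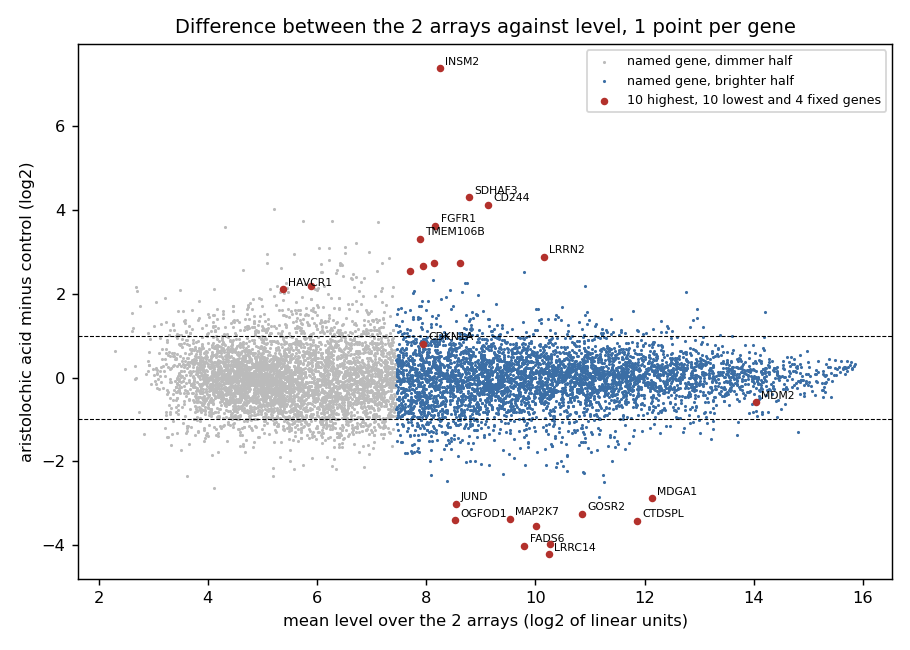
Log2 difference between the aristolochic acid array and the control array against the mean log2 level of both arrays, with 1 point per named gene and dashed lines at 2-fold; blue points are the 4637 brighter genes, and red points are the 10 highest, the 10 lowest and HAVCR1, ATF3, CDKN1A and MDM2. INSM2 at 7.38 lies far above all other named genes, and LRRC14 at -4.22 is the lowest of the brighter genes.

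Of 34 genes chosen for what is known of aristolochic acid and tubular injury, 22 had a named probe and 12 of these were among the brighter genes. Over all named genes, 545 of 9273 were at least 2-fold higher and 584 at least 2-fold lower. Of the 22 chosen genes, 3 were at least 2-fold higher, none was at least 2-fold lower, and all 3 were dim. They were ATF3, a stress-induced transcription factor (125.8 against 27.7 linear units, log2 difference 2.18), HAVCR1, which encodes the tubular injury marker KIM-1 (86.3 linear units after aristolochic acid, 2.11), and DDIT3, a transcription factor of the integrated stress response (106.0 against 42.3, 1.33). Among genes of the same bin of level, the difference of HAVCR1 stood at percentile 99.0, that of ATF3 at percentile 98.0 and that of DDIT3 at percentile 94.1. Their control levels were near the lower end of the scale, and with the same pseudocount the differences were 1.35 for ATF3, 1.13 for HAVCR1 and 0.86, below 2-fold, for DDIT3. OGG1, XRCC1, PARP1, NQO1, TXNRD1, SPP1, VIM, PCNA and SLC22A6 were among the genes not analysed here, as no probe carried their names in the reference.

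DNA damage is the best known effect of aristolochic acid, which forms adducts on purines. CDKN1A, a cell cycle inhibitor induced by DNA damage, was 1.74-fold higher (325.5 against 187.0 linear units), and the death receptor gene FAS was higher by 0.60 on the log2 scale. MDM2, a ubiquitin ligase gene, was lower with a log2 difference of -0.59 (13643 against 20531), and EDA2R had -0.61. The pro-apoptotic genes BBC3 and BAX lay close to 0, at 0.05 and -0.05. CDKN1A, FAS, MDM2, EDA2R, BBC3 and BAX all lay inside the central 95% of the differences of the brighter genes, from -1.38 to 1.13. GDF15, a stress-induced cytokine gene, and GADD45A, a damage-induced arrest gene, were dim, with -0.69 and -0.24. A second probe of GDF15 had 0.20.

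Nucleotide excision repair removes bulky adducts, and 7 of its 9 brighter genes had values above 0. MMS19 differed by 0.68, ERCC1 by 0.66, the damage sensor gene DDB2 by 0.54, ERCC3 by 0.38 and XPC by 0.09. The median of 0.34 lay at percentile 95.8, inside the central 95% of random lists. Dim members went both ways: RAD23B had 1.01, GTF2H3 0.58 and ERCC2 0.16, against GTF2H5 at -0.94, RPA3 at -0.92 and CCNH at -0.83. The lowest median of this list in the alternatives was 0.14. Mismatch repair, with 4 measured genes that were all above 0, had a median of 0.48 (percentile 94.4), led by EXO1 at 0.70 and the dim MSH6 at 0.58. Base excision repair had a median of -0.08 (percentile 29.4), with the glycosylase genes MUTYH at -1.34 and MPG at -0.79 and the endonuclease gene APEX1 at 0.41.

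In homologous recombination and Fanconi anaemia, BRCA1 was higher by 0.90 (2724 against 1458 linear units) and FANCC by 0.77, whereas MUS81 had -0.86, BRCA2 -0.79 and FANCF -0.71. Dimmer second probes of BRCA2 and FANCF had the other sign, at 0.37 and 0.25. The median of these 13 brighter genes was -0.23 (percentile 10.7), and 0.28 among the brightest 25% of genes. Non-homologous end joining had a median of 0.09 over 5 measured genes (percentile 63.2), with XRCC6 at 0.76 and the dim DCLRE1C at 0.69. The 6 brighter DNA damage checkpoint genes all lay within 1.5-fold, CHEK1 at 0.16 and ATR at -0.07 among them, with a median of 0.05 (percentile 56.6).

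Replication-dependent histone genes went both ways, with a median of -0.45 at percentile 2.46 of random lists, over all 8 measured members. Of these, 4 were at least 1.5-fold lower and 2 at least 1.5-fold higher. The linker histone gene H1-4 had -0.70 and H3C2 -0.59, while among the dim members H2BC12 had -0.92, H2AC6 1.26 and H2AC20 0.88, and the mean over the members was -0.10. DNA replication genes had a median of -0.32 (percentile 8.12), which turned to 0.41 among the brightest 25% of genes. The helicase subunit genes MCM2 and MCM6 had -1.36 and -0.61, the polymerase gene POLE -1.14 and the ribonucleotide reductase gene RRM2 0.62. The dim helicase subunit genes went both ways, with MCM3 at 1.08 and MCM4 at 0.39 against MCM7 at -1.20 and MCM5 at -0.14. Mitotic genes went both ways around a median of -0.17 (percentile 16.7): CCNB1 had -0.58, NDC80 -0.67 and NUF2 -0.63, while KIF23 was higher by 1.35 and CCNB2 by 0.84. Cell cycle inhibitors and arrest genes had a median of 0.20 (percentile 88.3), with CDKN2A at 0.59 and CDKN2D at -0.68. The histone list stayed outside the central 95% of random lists in 5 of 10 alternatives, and its percentile was 34.7 with the mean of the members.

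NRF2 targets and antioxidant enzymes had a median of 0.42 at percentile 98.2 over 8 brighter genes. CBR1, a carbonyl reductase, was higher by 1.02, with 0.90 on its second probe, and the sulfiredoxin gene SRXN1 by 0.97. AKR1B10 had 0.54, the ferritin light chain gene FTL 0.50 and GCLM, a subunit of the enzyme that limits glutathione synthesis, 0.34, while HMOX1 had -0.05 and AKR1C3 -0.25. Of the 8 genes, 2 were at least 1.5-fold higher and none at least 1.5-fold lower. Among the brightest 25% of genes the median of this list was -0.05, at percentile 38.0, and without a filter on level the list stood at percentile 94.3.

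Superoxide, peroxide and glutathione enzymes had a median of 0.22 (percentile 90.2), which was -0.04 at its lowest in the alternatives, with MSRB2 at 0.86, GSTT1 at 0.68, GSTP1 at 0.62 (-0.13 on its second probe), MGST1 at -0.60 and GSTM3 at -0.59. The list set for reduction and conjugation of aristolochic acid had a median of 0.36 (percentile 96.1) over its 6 measured genes. The cytochrome b5 reductase gene CYB5R3 at 0.72 and CYP1A2 at 0.54 were the highest. No sulfotransferase or N-acetyltransferase gene of the list had a named probe, nor had NQO1 or POR. Whether each of the 6 acts on aristolochic acid was not tested. CYP1A1 was high in both arrays, at 10273 linear units after aristolochic acid and 8776 in the control. It differed by 0.23 and CYP1B1 by -0.35. The 5 brighter genes of the aryl hydrocarbon receptor list all lay within 1.5-fold, with a median of 0.23 (percentile 86.1). They include the receptor gene AHR itself at 0.25 and the gene of its partner, ARNT, at -0.14. The 3 measured metal response genes had a median of 0.01 (percentile 50.1).

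Hypoxia response genes had a median of -0.63 at percentile 2.21 over 7 brighter genes, 4 of them at least 1.5-fold lower and 1 at least 1.5-fold higher. MXI1, an antagonist of MYC, had -1.58, the transcription factor gene BHLHE40 -0.99, INSIG2, a regulator of sterol synthesis, -0.85 and the endoplasmic reticulum oxidase gene ERO1A -0.63. LOX, the collagen crosslinking enzyme, was higher by 1.40 and HK2 by 0.34. Among the dim members ADM was higher by 2.17, while EGLN3 had -1.38. The list moved inside the central 95% of random lists among the brightest 25% of genes (percentile 3.97) and with the mean of its members (percentile 10.4). Glycolysis genes had a median of -0.19 (percentile 22.9), ALDOA at -0.66 and ALDOC at -0.54 being the lowest of the 6.

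With these 42 lists, 41 had enough measured genes for a value, and 3 of them, the NRF2, hypoxia and histone lists, lay outside the central 95% of random lists, where chance alone gives 2.05 on average. The lists were small, with between 3 and 27 genes each. In 7 lists the median and the mean had different signs, and 20 of the 41 lists kept the sign of their median under every alternative run.

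Immediate early genes and MAPK feedback genes had a median of -0.08 (percentile 32.7) with a wide spread. All 3 JUN family genes had values below 0, JUND at -3.01, JUN at -1.13 and JUNB at -0.74, as did KLF6 at -1.08 and DUSP4 at -0.81, while EREG, a ligand of the epidermal growth factor receptor, was higher by 2.06. Second probes of KLF6 and DUSP4 had the other sign, at 1.70 and 0.58. In the unfolded protein response, the chaperone gene PDIA4 was 2.83-fold higher, CALR was higher by 0.75 and CRELD2 had -0.72, around a median of -0.28 (percentile 12.4). That median turned to 0.59 (percentile 98.6) among the brightest 25% of genes, and the mean over the members was 0.00. Dim members of this list went both ways, with HERPUD1 at 1.33 against DNAJC3 at -1.51, CANX at -1.32 and ATF6 at -1.31. ATF4 and amino acid response genes had a median of 0.12 (percentile 69.3), and from -0.15 to 0.28 over the alternatives, with ALDH1L2 at 1.62 and MTHFD2 at -0.89. Of the 10 brighter heat shock genes, HSPA8 at 0.74 was the 1 beyond 1.5-fold, the dim HSPA4 had 1.07, and the median was 0.06 (percentile 62.9). Apoptosis regulators had a median of -0.07 (percentile 29.8), with the death receptor inhibitor CFLAR at 1.26, BCL2L11 at 0.91, APAF1 at -0.96 and BAD at -0.92. Autophagy and lysosome genes had a median of 0.09 (percentile 70.7), with ATP6V1A at 0.67 and GABARAPL2 at -0.82.

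Interferon-stimulated genes had a median of -0.51 at percentile 2.65, just inside the central 95% of random lists, and it stayed inside in 5 of 9 alternatives. All 8 brighter members were below 0, IFIT2 at -1.01, the signalling gene IRF9 at -0.69 and the RNA sensor gene IFIH1 at -0.68 being the lowest, while ISG15 had -0.04. The dim members were mixed, with IFI27 at 1.61 and IFITM1 at 1.41 against EPSTI1 at -1.19 and RIGI at -0.52. At its weakest in the alternatives the median of the interferon list was -0.17. NF-kB targets and inflammatory cytokines had a median of 0.10 (percentile 68.6), which was -0.21 at its lowest in the alternatives. The monocyte chemokine gene CCL2 had -0.49, with -0.10 on its second probe, complement C3 had 0.61, and CXCL8, the neutrophil chemokine gene, was dim at -0.85. TGF-beta targets and matrix genes had a median of -0.14 (percentile 20.7), which reached 0.23 in the alternatives, with LOX at 1.40, MMP10 at 0.87 and INHBA at -1.26. CCN2, a profibrotic TGF-beta target, was dim and differed by 0.32. Genes of epithelial-mesenchymal transition had a median of 0.22 (percentile 86.6), which was -0.04 at its lowest in the alternatives. CLDN1 had 0.82 and DSP 0.76, against ITGB6 at -0.47 and TWIST1 at -0.46. CDH1, the epithelial cadherin gene, was dim at -0.07.

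All 6 brighter cholesterol synthesis genes were below 0, ACAT2 at -1.49 and IDI1 at -1.15 being the lowest, and their median was -0.45 (percentile 5.05). A dim second probe of ACAT2 had 0.14. Of the dim members, MVK had 0.81 and DHCR7 0.40, against FDFT1 and INSIG1 at -0.62 each. The median of this list was -0.14 at its weakest in the alternatives. Fatty acid synthesis and oxidation had a median of -0.26 (percentile 10.99), with ACACB at -1.08. Oxidative phosphorylation had a median of 0.22 (percentile 90.9), with CYC1 at 0.74 and COX6C at -0.71. The median was 0.48 for cytosolic ribosomal proteins (percentile 96.4, 7 measured genes) and -0.04 for mitochondrial ribosomal proteins (percentile 34.6, 27 brighter genes, 0.05 with quantile normalisation). Only 2 proteasome genes had a named probe, too few for a value.

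Among kidney genes, proximal tubule transporters and enzymes had a median of -0.09 (percentile 35.2). PCK1, a gluconeogenic enzyme, had 0.83, the endocytic receptor gene CUBN 0.60 and the brush border peptidase gene ANPEP -0.61, and LRP2, which encodes megalin, was near the lowest levels in both arrays at 13.7 and 19.9 linear units. Tubular injury markers had a median of -0.30 (percentile 9.45), with HAVCR1 at 2.11 and ANXA1 at 0.71 against LCN2 and KRT7 at -1.03 each. HAVCR1, LCN2 and KRT7 were dim, as were 6 of the 8 members, and the mean over the members was 0.00. Genes of the loop, distal tubule and collecting duct had a median of 0.00 (percentile 48.5), whose sign turned with every scaling tried. Markers of other cell types lay within the random range: fibroblast -0.23 (percentile 15.5), endothelial 0.20 (percentile 77.1), haematopoietic -0.08 (percentile 36.9) and keratinocyte -0.07 (percentile 39.8). Housekeeping genes had a median of 0.31 (percentile 90.9).

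**Figure D2:**
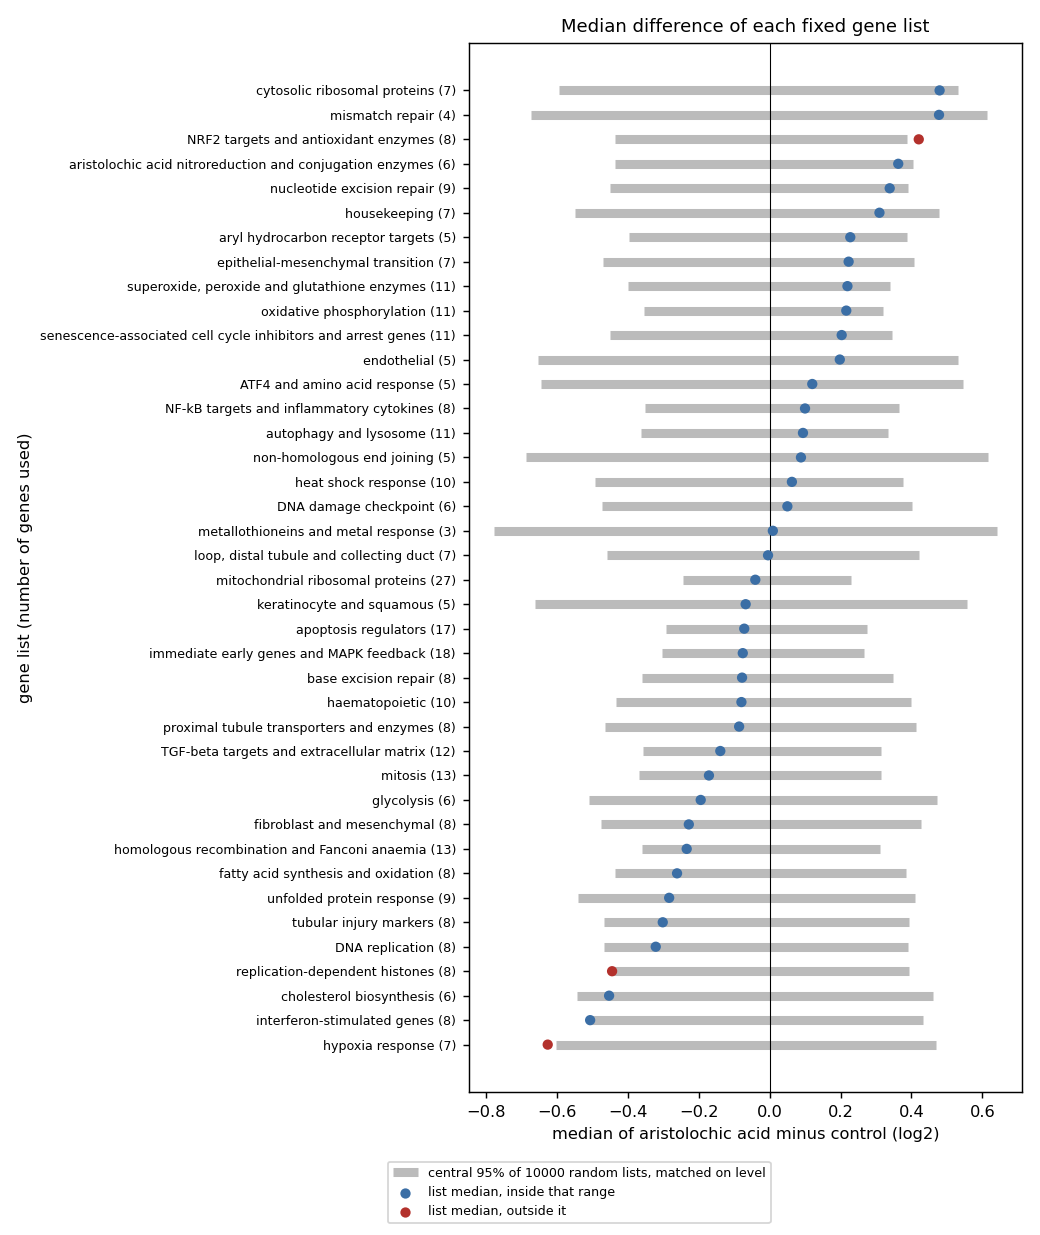
Median log2 difference between the aristolochic acid and control arrays for 40 gene lists (points), with the central 95% of the medians of 10000 random lists of the same size and level (grey bars) and the number of genes used in brackets. The NRF2 list at 0.42 lies above its bar, and the histone list at -0.45 and the hypoxia list at -0.63 lie below theirs.

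Repeat probes of a gene gave the one check of a gene's difference within this pair of arrays. Over 692 brighter genes with at least 2 probes, the differences of the 2 brightest probes correlated across genes with a Pearson r of -0.01 and a Spearman rho of 0.00, and 51.0% of the pairs had the same sign. The central 95% of random pairings of the same probes gave r from -0.07 to 0.08. Genes are not independent replicates in this count. INSM2, LRRC14 and JUND had a single probe each, so their differences had no repeat, and each value stands for the probe that carries the gene's name.

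**Figure D3:**
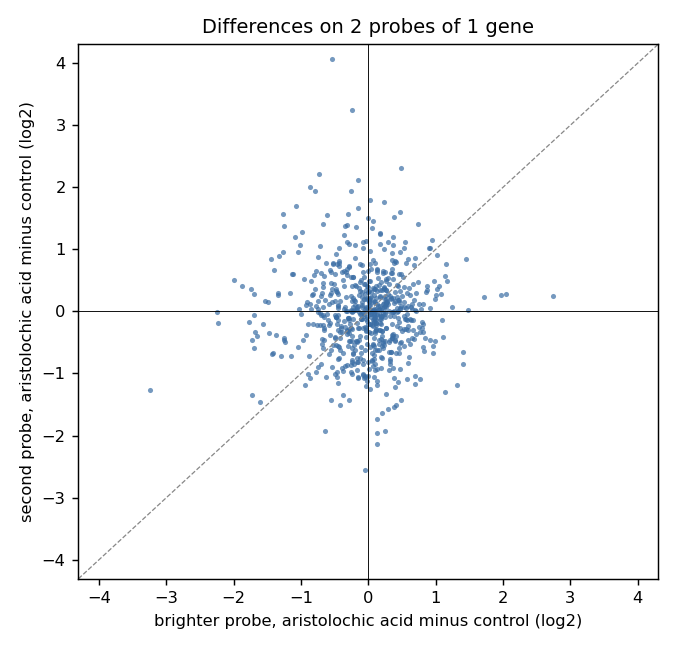
Log2 difference on the second brightest probe of a gene against the difference on its brightest probe, for 692 brighter genes with at least 2 probes; the dashed line marks equal differences. The points form a round cloud about 0 with r = -0.01, and GOSR2 is the point at -3.25 and -1.26.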

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

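The tests on probe agreement below were chosen after that agreement had been seen, and the count of probes without a gene name was added after the other results, whereas the loess test of the lower and higher counts and the test of chance among the lists were set before their results.

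Probes without a gene name, which enter none of the comparisons above, also differed between the arrays. Of the 4968 such probes at or above their own median level, 246 (4.95%) were at least 2-fold higher after aristolochic acid and 256 (5.15%) at least 2-fold lower, with extremes of 4.73 and -4.49 on the log2 scale.

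More of the brighter named genes were at least 2-fold lower than higher, 281 against 170, a ratio of 1.65 (95% exact binomial interval over genes 1.36 to 2.01, which covers counting only). A trend of the central difference with level is argued against as the whole cause. The ratio was still 1.53 (1.27 to 1.86) once loess had removed that trend. Loess shifts only the centre of the differences, so it could not test a skew of the differences that changes with level. The split did change with level. The ratio was 1.07 over all named genes without the filter, 1.65 among the brighter genes and 1.87 among the brightest 2319. Among the dimmer named genes alone, more were at least 2-fold higher than lower. Such a skew therefore stays open as a cause, and its origin was not tested. The choice of probes with a name remains open, since probes without one gave a ratio of 1.04 (0.870 to 1.24). That ratio counts single probes above their own median level, not 1 probe per gene above the median of named genes. It is therefore not a like for like comparison with 1.65. Having a name is not enough by itself, as all named genes without the filter on level gave 1.07 (584 against 545), so the excess, with LRRC14, CASKIN2 and JUND in it, may depend on which probes are counted. An effect of aristolochic acid itself is confounded with the arrays and was not tested.

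The differences on repeat probes of a gene did not follow each other. Names assigned wrongly throughout are argued against, as the levels of both probes correlated with r = 0.13 while 100 shifted pairings reached 0.08 at most, but wrong names for part of the probes were not tested. Noise of dim probes as the sole cause was set to need r of 0.5 or more, a bound written after the data had been seen, and the 66 genes with both probes among the brightest 25% had r = 0.20 (bootstrap interval -0.08 to 0.45), inside the central 95% of random pairings (-0.23 to 0.25). Of these 65.2% shared the sign, against 53.1% of the 260 genes with both probes brighter (r = -0.10), a difference that was not tested, so such noise stays open as part of the cause. Whether there were too few real differences for both probes to show cannot be told apart from the other causes, since just 15 genes had a brightest probe beyond 2-fold and a bright second probe, and 7 of these (46.7%, interval 21.3% to 73.4%) shared the sign.

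The median of the NRF2 list lay above the central 95% of random lists and those of the hypoxia and histone lists below it. Chance remains open for this count of 3: when differences were reassigned at random among genes of like level, a share of 0.353 of 1000 reassignments had at least as many lists outside, with a median of 2. These lists are hypotheses for a design with replicates, and an effect of aristolochic acid on them was not tested.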

How the results depend on the processing

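The alternatives for both bright probes of a gene and for probes without a name were chosen after seeing the data; the others were planned. Leaving out an array leaves no comparison. The counts of 170 higher and 281 lower genes stayed within 1.5 times under each of the scalings, the mean of probes and the pseudocount. They were 545 and 584 without a filter on level, 55 and 103 in the brightest 25%, 579 and 761 at 1.5-fold, and 39 and 68 at 3-fold, where the alternative itself takes in more or fewer genes. Of 41 lists, 33 kept their side of the central 95% under every alternative run and 20 kept their sign; 12 lists had too few genes in the brightest 25%. For lists that crossed it, the percentiles were as follows, and the cause was not tested. Interferon genes moved outside at 2.35 with loess, 2.32 with the pseudocount, 1.91 without matching and 1.97 with 20 bins, nucleotide excision repair at 98.3 with the mean of probes, glycolysis at 2.46 without a filter, the unfolded protein response at 98.6 in the brightest 25%, and cholesterol synthesis at 1.44 with the mean of members. Histones moved inside at 2.65 with the mean of probes, 4.83 in the brightest 25%, 4.27 without matching, 2.68 with 20 bins and 34.7 with the mean of members, the NRF2 list at 94.3 without a filter and 38.0 in the brightest 25%, and hypoxia at 3.97 in the brightest 25% and 10.4 with the mean of members. Between 1 and 4 lists lay outside, 1 of them in the brightest 25%. Probe agreement was -0.10 with both probes bright. None of the 48 named genes turned sign across 2-fold in 5 alternatives; SRXN1 passed 2-fold with loess (1.02), while CBR1 was below it with the mean of probes (0.96) and the pseudocount (0.96), and DDIT3 with the pseudocount (0.86). No signal over background was used, so dim genes such as HAVCR1 are the least certain.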

Other observations

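The grouping by symbol in this part was chosen after the data had been seen.

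Over 17 brighter genes with a symbol starting in ARHGAP the median log2 difference was -0.39, at percentile 0.635 of random lists of the same size and level, with 6 genes at least 1.5-fold lower and 1 at least 1.5-fold higher. ARHGAP15 had -0.93, ARHGAP4 -0.86, ARHGAP24 -0.72 and ARHGAP45 -0.68, while ARHGAP26 was higher by 0.99. Of 29 symbol groups with at least 12 brighter genes this was the 1 group outside the central 95%, where chance gives 1.45 on average. Symbols with the stems C, LOC, FAM, TMEM, KIAA, ORF and CCDC were left out by choice, and no value was computed for them. Long intergenic noncoding RNAs (LINC symbols, 22 genes) had a median of 0.24 at percentile 97.3. Matrix metalloproteinases (12 genes) had -0.25 at percentile 4.59, and genes with COX symbols (14 genes) had -0.26 at percentile 4.62.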
